A study of Mus musculus with 17 samples.

How the data were processed

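RNA was measured in 17 libraries of small-intestinal epithelial cells from Igha -/+ mice. Per the labels' protocols, EpCAM+ CD45- Ter119- cells were sorted and frozen, thawed for RNA extraction once all groups had been collected, amplified with the SMART-seq v4 Ultra Low Input kit and made into Nextera XT libraries. The deposited table holds TPM values for 53278 gene symbols, with no identifiers beside them. Alignment to mm10, Bowtie2, Subread and DESeq2 are named, without versions or settings, per the submitters' processing notes. Each column summed to the same total over all genes, ribosomal and mitochondrial RNA included, with no scaling between libraries.

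TPM keeps no depth, but multiplying each value by the gene's exon length in GENCODE M21 (GRCm38/mm10) gave whole multiples of 1 step per library. A length was found for 49721 symbols, and 93.6% of the values above 0 came out whole within 0.01 reads or a relative tolerance of 1e-04. Among values under 100 reads the share was 95.3%, against 1.80% with shuffled lengths. The recovered reads gave each library's depth, and their number limits the precision of low genes. These reads are PCR products without molecular identifiers.

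The groups were the 6 combinations of dam and day of life as the titles give them. Genes with a TPM of at least 1 in at least 2 libraries were tested (15066 genes). The main test was limma 3.58.1 in R 4.3.3, with an intensity trend, on log2(TPM + 1) in 1 fit over all 17 libraries. Genes with a Benjamini-Hochberg adjusted p under 0.05 passed. Fold changes are therefore on the log2(TPM + 1) scale, which understates the change of low genes. Comparisons were the dams at each age, the dams averaged over ages, the difference of the dam effect between ages (a moderated F test), and adjacent ages within each dam. The TPM of most genes shifted together between some groups. Each main result is therefore given beside the value after division by median-of-ratios size factors, called scaled below.

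Gene lists for epithelial cell types, processes, segments and other cell types of the tissue were fixed from general knowledge. They numbered 32, and 29 had at least 2 members tested. The B and plasma cell, fibroblast and smooth muscle, and endothelium lists had 1 member each past the filter and were not tested. Lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry, adjusted over the lists of a comparison. A list's count of called genes is given over all genes and adjusted over the list alone.

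Named genes were chosen by rule. For a comparison between dams these were the 10 largest rises and 10 largest falls (5 and 5 for ages) among called genes whose libraries did not overlap, with a mean of at least 10 TPM in the higher group. Up to 4 members of each list with the smallest p, the check genes Igha, Pigr, Fcgrt, Epcam and Ptprc, and the 10 smallest adjusted p of the difference between ages were added. Predicted genes were left out of the ranking. Where no gene qualified, the 5 smallest p were named. An enterocyte maturation score was the mean log2(TPM + 1) of an adult list minus that of a neonatal list. It was compared with exact two-sided permutation tests in R 4.3.3. Reads were recovered in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3.

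The groups, tests, lists, naming rule and most alternatives were chosen before the data were examined. The alternatives were pseudocounts of 0.1 and 5, no filter, a TPM of at least 5, median-of-ratios scaling, quantile normalisation, TPM without mitochondrial and the 50 highest genes, robust moderation, library weights, only the compared groups, a replicate block, a covariate from Xist and Y-linked genes, and leaving out each library. Added after seeing the data were limma-voom on the recovered reads, leaving out each library after scaling, and leaving out pairs of doubted libraries. No library was left out of the main results.

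The limma test was tested on simulated data with known changes in the design of each comparison. Every gene was given the same dispersion (0.0505), and only genes with many reads were changed. No shift in composition and no outlying library was simulated, so the shares below need not hold for the real libraries. At day 14 it recovered 1.49% of genes changed 1.5-fold, 17.9% changed 2-fold and 83.3% changed 4-fold, of 12499 genes tested. At day 24 these shares were 0%, 1.49% and 84.8%, and at day 42 they were 1.49%, 23.9% and 92.4%. Calls of unchanged genes were 11 of 79 at day 14 and 5 of 83 at day 42, both above a share of 0.05, and 1 of 58 at day 24.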

Results

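Gene expression was measured in small-intestinal epithelial cells of Igha -/+ pups, which can make IgA themselves, nursed by a C57BL/6 dam (B6 dam) or by a dam without IgA (IgA-null dam). Cells were taken on days of life 14, 24 and 42, so that the comparison of the dams at each age asks what maternal IgA changes in the developing epithelium. Each group had 3 libraries, except the B6 dam group at day 24, which had 2. Recovered depth ran from 11078968 to 13297365 reads per library at day 14 with the B6 dam and from 8251505 to 11024031 with the IgA-null dam. The day 24 libraries held 17655069 and 16858082 reads with the B6 dam and 11577248 to 14015676 with the IgA-null dam. Day 42 libraries held 14833675 to 17085616 and 15029365 to 16527585 reads. The labels do not say which pups shared a litter or a dam, so p-values measure the spread between these samples only. The dates in the labels differed between the dams at days 14 and 24 and were the same at day 42. Within each dam they differed between ages, except between days 24 and 42 with the IgA-null dam. Where the dates differ, an effect of the date cannot be told apart from the comparison.

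A 57 bp gene model, Gm23935, took 40.2% to 61.9% of TPM in each library, and the mitochondrial ribosomal RNAs took 12.8% to 31.9%. What remained outside Gm23935 and all mitochondrial genes was 19.3% ± 0.434 at day 14 with the B6 dam and 28.2% ± 3.18 with the IgA-null dam (SD, n = 3 each). At day 24 it was 18.4% and 15.9% in the B6 dam libraries and 12.4% ± 2.49 with the IgA-null dam. Rn7sk, a small nuclear RNA that holds back transcription elongation, was listed at 31142 ± 3414 TPM at day 14 with the IgA-null dam and 6794 ± 1151 with the B6 dam (SD, n = 3 each). Median-of-ratios size factors on TPM ran from 0.477 to 1.83. The scaling moved the median log2 fold change of all genes from 0.33 to -0.01 at day 14 and from -0.38 to -0.03 at day 24.

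Epcam, the epithelial adhesion molecule used for the sort, lay between 153 and 500 TPM in the 17 libraries. Ptprc, which encodes the leukocyte antigen CD45 that the sort excluded, stayed at or below 0.806 TPM, and Igha stayed at or below 0.684 TPM. Ddx3y, a Y-linked gene, was found in every library (2.46 to 9.50 TPM), and Xist, the RNA of the inactive X, reached 0.127 TPM. Fcgrt, the neonatal Fc receptor that takes up milk IgG, was at 370 ± 196 TPM at day 14 with the B6 dam and 184 ± 70.4 with the IgA-null dam (SD, n = 3 each), and this difference did not pass (adjusted p = 0.13). Pigr, which carries IgA across the epithelium, was at 210 ± 53.4 and 351 ± 51.5 TPM in the same groups (adjusted p = 0.076).

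At day 14, most tested goblet and enteroendocrine genes were higher in pups of IgA-null dams than in pups of B6 dams, and the largest ranked rise was that of Reg3b. Reg3b, an antimicrobial lectin (chromosome 6, 78370657 to 78373466, GRCm38), rose from 2.79 ± 0.866 to 74.9 ± 39.5 TPM (log2 fold change 4.23, SE 0.48, adjusted p = 0.00077). Zg16, a goblet cell lectin that binds bacteria (chromosome 7, 127050156 to 127087328), rose from 14.9 ± 5.90 to 206 ± 120 TPM (3.63, SE 0.43). Chga, a granule protein of enteroendocrine cells (chromosome 12, 102554969 to 102565028), rose from 24 ± 3.9 to 222 ± 38.5 TPM. The gut hormones neurotensin (Nts, 28.0 ± 17 to 218 ± 61.5 TPM) and Gip (44.5 ± 6.02 to 354 ± 96.8 TPM) and the granule protein Chgb (67.1 ± 8.0 to 462 ± 73.5 TPM) rose with it, as did Slc39a7, a zinc transporter of the secretory pathway (2.09 ± 0.390 to 18.3 ± 3.69 TPM; SD, n = 3 each). These 7 genes passed in both scalings and, as deposited, with each single library left out. Reg3g, a close relative of Reg3b, went from 1.09 ± 0.325 to 20.1 ± 22.0 TPM (log2 fold change 2.83, adjusted p = 0.0084). Without IgA-null dam replicate 1, which held 45.5 TPM, its log2 fold change was 2.01, and after scaling its adjusted p was 0.052. The Paneth cell products Defa20 and Mptx2 (2.84 and 2.74 on the log2 scale) passed as deposited only, with scaled adjusted p of 0.17 and 0.16, and both lost the call without B6 dam replicate 1 (adjusted p = 0.094 and 0.12) and without at least 3 other libraries. Reads of these defensin, Mptx and Reg3 paralogs are hard to assign, so their values are uncertain.

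Of the ranked falls with the IgA-null dam at day 14, the largest was that of Gpx3, a secreted glutathione peroxidase (chromosome 11, 54902453 to 54910377), from 378 ± 256 to 34.9 ± 13.6 TPM (log2 fold change -3.17, SE 0.45, adjusted p = 0.0015). The lysosomal proteases Lgmn (133 ± 95.0 to 13.4 ± 5.64 TPM) and Ctsl (59.7 ± 40.5 to 7.21 ± 2.68 TPM) fell by 2.98 and 2.64 on the log2 scale. Meltf, a surface iron-binding protein, fell from 154 ± 97.2 to 36.2 ± 14 TPM (SD, n = 3 each). These 4 genes passed in both scalings and, as deposited, with each single library left out. Without B6 dam replicate 3, which held the lowest level of its group, the log2 fold changes were -3.85 for Gpx3, -3.65 for Lgmn, -3.31 for Ctsl and -2.49 for Meltf. The remaining ranked falls, Npl, S100a1, Slc46a3, Folr1, Ctsa and Cym, lay between -1.88 and -1.19. All 6 lost the call without B6 dam replicate 1 (adjusted p from 0.051 for Folr1 to 0.12 for Slc46a3), and all but Folr1 lost it without at least 2 other libraries as well.

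Of the goblet list, 18 of 20 tested members rose at day 14, and 18 adjusted over the list alone. They included Tff3, a trefoil peptide of mucus (144 ± 23.7 to 697 ± 176 TPM), Muc2, the gel-forming mucin (58.2 ± 10.4 to 276 ± 71.5 TPM), and Fer1l6 (1.91 ± 0.191 to 8.14 ± 1.87 TPM; SD, n = 3 each). Of the enteroendocrine list, 17 of 20 rose (18 adjusted over the list alone), with Pyy, a satiety hormone, from 5.52 ± 1.93 to 37.6 ± 6.64 TPM and Tph1, which makes serotonin, from 0.942 ± 0.253 to 7.33 ± 2.51 TPM. The median log2 fold change was 1.65 for the goblet list and 2.12 for the enteroendocrine list, or 1.19 and 1.65 after scaling, where 13 and 14 members rose in both scalings. Paneth cell genes rose in 5 of 18 members (6 adjusted over the list alone, 2 in both scalings), among them Mptx1 and the protease Mmp7. Tuft cell genes rose in 6 of 17 (12 adjusted over the list alone, 2 in both scalings), with Sh2d6 at 0.530 ± 0.0906 and 4.39 ± 0.968 TPM. All 4 lists passed camera as higher, and none held with an estimated correlation: adjusted p = 0.27 for goblet and enteroendocrine and 0.72 for Paneth and tuft. By fry, run only as deposited, the goblet (adjusted p = 0.0040) and enteroendocrine (0.0070) lists moved 1 way. Of the microbe-responsive list, which holds Reg3b and Reg3g, 4 of 15 rose (6 adjusted over the list alone); camera gave adjusted p = 0.12 and fry 0.0083.

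The neonatal enterocyte list was lower at day 14: 3 of 18 members fell (5 adjusted over the list alone, 14 after scaling), with a median of -0.65 (scaled -1.05). Camera called it lower, with adjusted p = 0.10 with an estimated correlation. The interferon-stimulated (median -0.12), mitochondrially encoded (-0.53), T cell (-0.16) and enteric neuron (-0.22) lists were called lower by camera, with adjusted p = 0.51, 0.26, 0.27 and 0.26 with an estimated correlation. Camera also called the adult enterocyte, peptide uptake, fat absorption and macrophage lists lower although their medians were 0.27, 0.12, 0.08 and 0.10 (scaled -0.0019, -0.31, -0.34 and -0.08), since it ranks a list against all other genes. With an estimated correlation their adjusted p were 0.72, 0.72, 0.67 and 0.27, and the means of the fat absorption (-0.05) and macrophage (-0.27) lists were negative. After scaling, camera called none of these 4 lists (adjusted p = 0.74, 0.53, 0.10 and 0.38), nor the T cell list (0.38). None of these 8 lists had more than 1 called gene, over all genes or adjusted over the list alone. Without B6 dam replicate 1 the adult enterocyte and peptide uptake calls were lost (adjusted p = 0.069 and 0.071), as they were without IgA-null dam replicates 3 (0.063) and 2 (0.055), and the macrophage call was lost without IgA-null dam replicate 1 (0.14). Of the genes in the leukocyte lists, Csf1r, the receptor for the macrophage growth factor, fell from 4.31 ± 3.13 to 0.556 ± 0.20 TPM. Trac, the T cell receptor alpha constant gene, fell from 2.22 ± 0.851 to 0.619 ± 0.331 TPM (SD, n = 3 each). Ptprc was at 0.0504 TPM with the B6 dam and 0.0508 with the IgA-null dam, so these falls do not show fewer leukocytes. Trac lost the call after scaling (adjusted p = 0.061) and without B6 dam replicate 1 (0.11) or 3 other libraries. The median for stem cell genes was 0.19 (scaled -0.23), with 1 of 17 called higher, and for cell cycle genes 0.43 (scaled 0.01), with 1 of 28 (0 in each adjusted over the list alone). The proximal and distal segment lists had medians of 0.20 and 0.29 (scaled -0.23 and -0.04), with 1 and 4 of 15 members called higher (1 and 4 adjusted over the list alone). Called members of the remaining lists were few: electron transport (median 0.39) 2, and cholesterol synthesis (0.32), aryl hydrocarbon (0.28), immediate early (0.48) and unfolded protein response (0.62) 1 each. Adjusted over the list alone these counts were 0, 1, 2, 1 and 9. The MHC class II (0.12), circadian (0.34), tight junction (0.26), M cell (-0.08), erythroid (-0.06) and pancreas (-0.21) lists had none.

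In total, limma called 1307 of 15066 genes at day 14, 1253 higher and 54 lower with the IgA-null dam, and 638 of these changed at least 2-fold. After scaling it called 442 genes, 270 higher and 172 lower. The share higher was therefore 95.9% as deposited and 61.1% scaled, and 308 genes passed in both (270 higher, 38 lower). Limma-voom on the recovered reads called 416 genes (270 higher), of which 293 were among the deposited calls. Left out singly, B6 dam replicates 1, 2 and 3 gave 324, 450 and 756 genes, and IgA-null dam replicates 1 and 3 gave 480 and 418. With scaling, 5 of the 6 libraries left out singly gave fewer genes: 82 and 88 without B6 dam replicates 1 and 2, and 111, 104 and 123 without IgA-null dam replicates 1, 2 and 3.

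**Figure D1:**
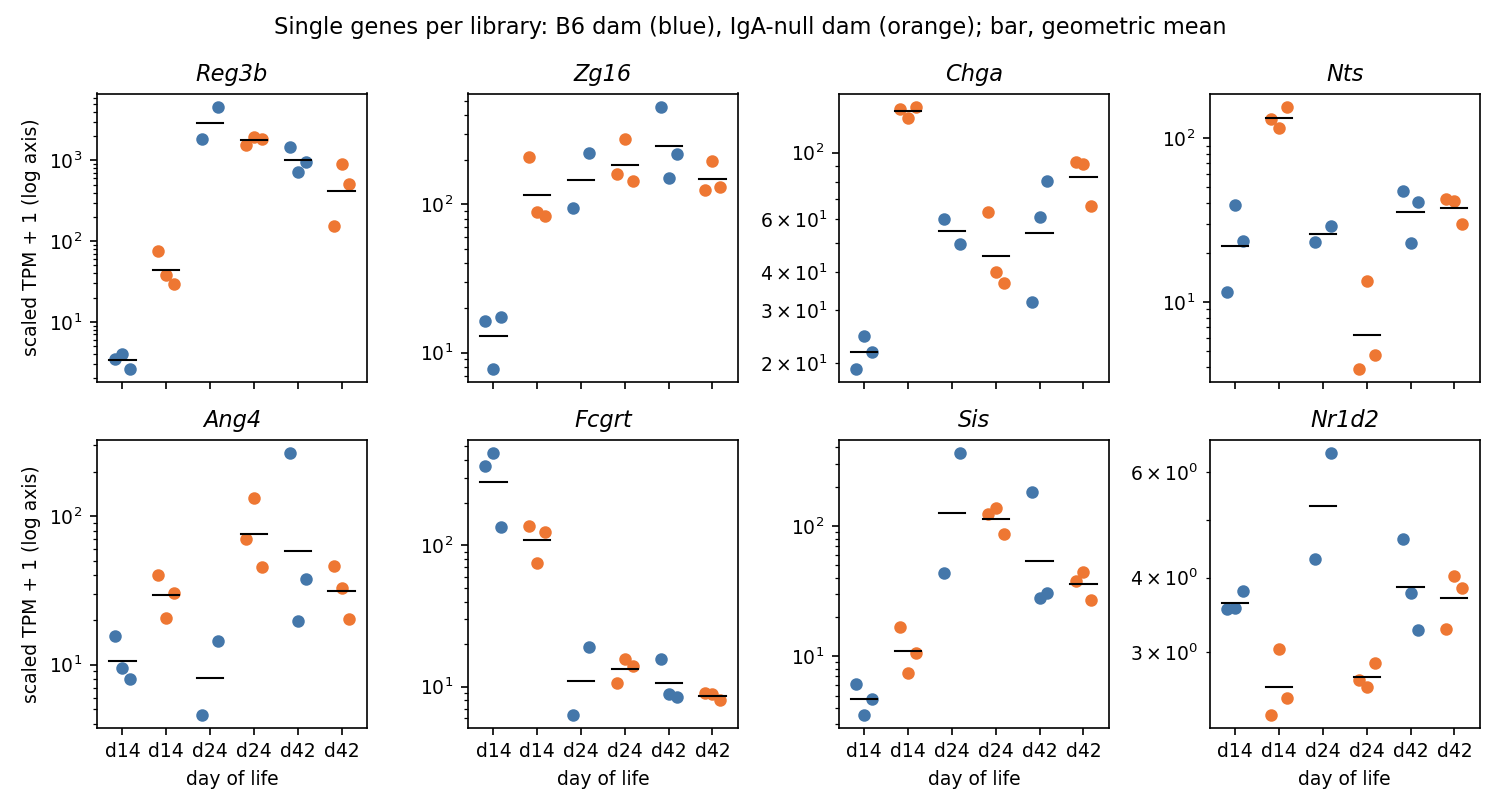
TPM + 1 after median-of-ratios scaling (log axis) of 8 genes in each of the 17 libraries, by dam (B6 blue, IgA-null orange) and day of life; bars are geometric means. At day 14 the Reg3b, Zg16, Chga and Nts points of the 3 IgA-null dam libraries lie above those of the 3 B6 dam libraries.

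At day 24, just after the usual age of weaning, the dams differed in few genes past the threshold. Nr1d2, a repressor in the circadian clock (chromosome 14, 18204054 to 18239127), fell from 3.55 and 3.67 TPM in the B6 dam libraries to 0.996 ± 0.189 TPM with the IgA-null dam (SD, n = 3; log2 fold change -1.21, SE 0.15, adjusted p = 0.0065). Car4, a carbonic anhydrase of the enterocyte membrane (chromosome 11, 84957786 to 84966044), fell from 13.0 and 13.8 to 4.09 ± 1.06 TPM (-1.52, adjusted p = 0.0082). Slc35g1 fell from 15.1 and 15.8 to 6.44 ± 0.164 TPM (adjusted p = 0.047). Usp2, a deubiquitinase with a daily rhythm, was the only other called gene and is named after its values were seen (-0.99, adjusted p = 0.047). After scaling none of the 4 passed, with adjusted p from 0.14 to 0.36, and limma called 0 genes (1520 at an unadjusted p under 0.05, against 4659 as deposited); limma-voom also called 0 (1314 unadjusted).

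Paneth cell genes were higher at day 24 with the IgA-null dam, with a median log2 fold change of 1.82 (scaled 2.38). None of 18 passed over all genes, and 12 passed adjusted over the list alone (16 after scaling). Ang4, an antimicrobial ribonuclease, was at 3.88 and 8.98 TPM with the B6 dam and 47.5 ± 25.3 with the IgA-null dam (adjusted p = 0.068). Itln1, a lectin, was at 135 and 110 against 474 ± 227 TPM (adjusted p = 0.075; SD, n = 3). Camera called the list higher, with adjusted p = 0.051 with an estimated correlation. Enteroendocrine genes were lower in 13 of 20 members adjusted over the list alone and in none over all genes (median -1.35, scaled -0.89; adjusted p = 0.76 with an estimated correlation). Nts was at 23.9 and 18.8 TPM with the B6 dam and 3.52 ± 2.74 with the IgA-null dam (adjusted p = 0.059). Mitochondrially encoded genes had a median of 0.46 (scaled 1.03, 10 of 13 higher adjusted over the list alone) and nuclear electron transport genes -0.73 (scaled -0.17). Of the latter, 31 of 42 were lower adjusted over the list alone as deposited and 0 after scaling. Adjusted p with an estimated correlation was 0.21 for the mitochondrially encoded list and 0.76 for the nuclear list. The unfolded protein response, tight junction and cholesterol synthesis lists behaved like the nuclear list, with 14, 13 and 13 members lower adjusted over the list alone and 0 each after scaling (adjusted p = 0.76 each with an estimated correlation). The count of 4 called genes was 4870 without B6 dam replicate 2, 2195 without IgA-null dam replicate 1 and 0 without IgA-null dam replicate 3. After scaling the count was 29 without B6 dam replicate 1, and 1 or 2 without any other library.

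At day 42 no gene differed between the dams past the threshold. Limma called 0 genes (174 at an unadjusted p under 0.05), 0 after scaling (243 unadjusted), and limma-voom called 0 (295 unadjusted). The 5 smallest p belonged to Ada, an adenosine deaminase (18.2 ± 7.11 against 6.05 ± 3.99 TPM), Gda, a guanine deaminase (32.0 ± 19.7 against 8.25 ± 5.76 TPM), Degs1, Agr3 and Hist1h2al, annotated as a processed pseudogene (SD, n = 3 each). None of these passed (adjusted p = 1.0 each). Tuft cell genes had a median log2 fold change of 0.55 and enteroendocrine genes 0.54, and camera called both lists higher, with adjusted p = 0.41 each with an estimated correlation. Paneth cell genes (median -0.88), interferon-stimulated genes (-0.23), fat absorption genes (-0.48) and adult enterocyte genes (-0.48) were called lower by camera, with adjusted p from 0.41 to 0.44 with an estimated correlation. No member of any of these lists passed, over all genes or adjusted over the list alone. Relative to the median of all genes, the list medians without B6 dam replicate 1 were -0.04 for Paneth, 0.04 for fat absorption and 0.22 for adult enterocyte genes. Camera then no longer called the Paneth (adjusted p = 0.26), fat absorption (0.67) and enteroendocrine (0.065) lists, and called the adult enterocyte list higher (0.017).

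**Figure D2:**
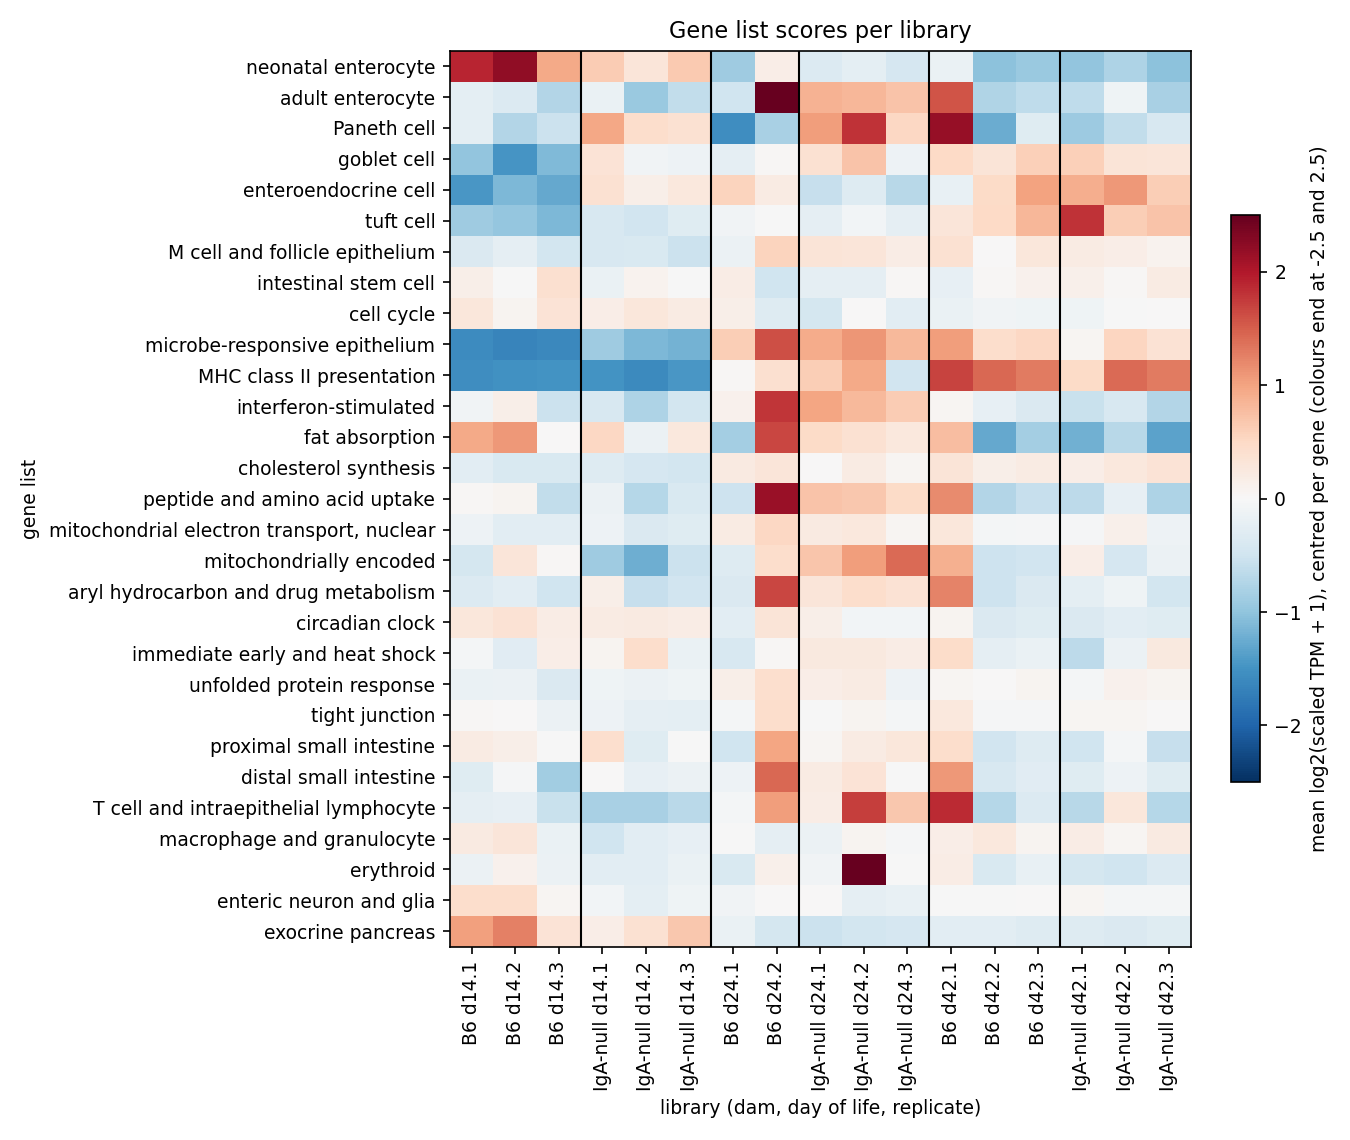
Scores of 29 gene lists (rows) in the 17 libraries (columns, by dam and day of life), as the mean log2(TPM + 1) of the members after median-of-ratios scaling relative to all libraries. The day 14 IgA-null dam libraries have higher goblet and enteroendocrine scores than the day 14 B6 dam libraries.

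Averaged over the 3 ages, no gene differed between the dams past the threshold. Limma called 0 genes (1280 at an unadjusted p under 0.05) and 0 after scaling (2175 unadjusted), while limma-voom called 14, all higher with the IgA-null dam (1943 unadjusted). The smallest p belonged to Nr1d2 (log2 fold change -0.47, adjusted p = 0.10), Mptx1 (1.03, 0.13), Gpx3 (-1.27, 0.20), Fer1l6 (0.57, 0.20) and the protease Lgmn (-1.23, 0.20), none of which passed. The goblet list was higher in 16 of 20 members adjusted over the list alone (median 0.56; adjusted p = 0.48 with an estimated correlation), with the mucin Muc2 at 0.82 (adjusted p = 0.21). Without B6 dam day 14 replicate 3 the count was 16, and without IgA-null dam day 24 replicate 2 it was 1. After scaling it reached 85 without B6 dam day 24 replicate 1, 54 without B6 dam day 14 replicate 3 and 40 without IgA-null dam day 24 replicate 2.

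The dam effect itself differed between ages in 264 genes by the moderated F test, and in 21 after scaling (20 in both). Limma-voom called 6, all among the 264. Reg3b had a log2 fold change of 4.23 at day 14, -1.30 at day 24 and -1.22 at day 42 (adjusted p = 0.0066, scaled 0.048), and the hormone Nts had 3.07, -2.46 and 0.14 (adjusted p = 0.0080, scaled 0.048). Across genes, the scaled dam effects at days 14 and 24 had a Pearson r of 0.218 (Spearman 0.258). Those at days 14 and 42 had 0.0726 (0.0948) and those at days 24 and 42 had -0.135 (-0.107). Genes are not independent replicates, so these are descriptions of 3 pairs of effects. Of the 308 genes called at day 14 in both scalings, 195 had the same sign after scaling at day 24 and 188 at day 42. The count of 264 ranged from 9 without B6 dam day 14 replicate 1 to 6555 without B6 dam day 24 replicate 2; it was 13, 18 and 20 without IgA-null dam day 14 replicates 3 and 1 and B6 dam day 14 replicate 2, and 1039, 1632 and 3938 without IgA-null dam day 14 replicate 2, B6 dam day 42 replicate 1 and IgA-null dam day 24 replicate 1. It was 26 without B6 dam day 24 replicate 1, 42 and 49 without IgA-null dam day 24 replicates 2 and 3, 50, 51 and 94 without IgA-null dam day 42 replicates 1, 2 and 3, 67 without B6 dam day 14 replicate 3, and 114 and 497 without B6 dam day 42 replicates 2 and 3.

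In pups of B6 dams, 10 of 15 genes of the microbe-responsive list were higher at day 24 than at day 14. Reg3b rose from 2.79 ± 0.866 TPM to 1986 and 3120 TPM (log2 fold change 9.39, SE 0.54, adjusted p = 1.9e-08), and Reg3g from 1.09 ± 0.325 to 505 and 749 TPM. Sis, the sucrase-isomaltase that splits dietary sugar (chromosome 3, 72888557 to 72967863), rose from 4.42 ± 1.36 to 45.9 and 243 TPM, with log2 fold changes of 5.53 and 3.15 without B6 dam day 24 replicate 1 and 2. Duox2, an oxidase that makes hydrogen peroxide at the epithelial surface (0.282 ± 0.0674 to 15.3 and 11.7 TPM), and Cd74, the MHC class II invariant chain (1.64 ± 0.336 to 31.1 and 20.5 TPM), rose as well. Falls were seen in Meltf, from 154 ± 97.2 to 0 and 0.0795 TPM, Cym, the milk-clotting protease, from 103 ± 7.62 to 0.0353 and 1.13, Mamdc4, an endocytic protein of the suckling gut, from 120 ± 63.1 to 0.914 and 0.505, and Fcgrt (chromosome 7, 45092990 to 45103851) from 370 ± 196 to 5.75 and 12.2 (SD, n = 3 at day 14).

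By list, 14 of 18 neonatal enterocyte genes fell between days 14 and 24 with the B6 dam (15 adjusted over the list alone; median -2.23, adjusted p = 0.18 with an estimated correlation). Of the microbe-responsive list, 10 of 15 rose (10 adjusted over the list alone; median 1.58), and this list held with an estimated correlation (adjusted p = 0.0032), but not after scaling (0.13). Of the enteroendocrine list 9 of 20 rose (17 after scaling), of interferon-stimulated genes 9 of 26 and of MHC class II genes 4 of 7 (14, 13 and 6 adjusted over the list alone). Their adjusted p with an estimated correlation was 0.19, 0.24 and 0.17. Clock genes fell in 7 of 15 members (8 adjusted over the list alone), with Per2 from 10.8 ± 1.94 to 1.56 and 1.96 TPM, and cell cycle genes fell in 7 of 28 (13 adjusted over the list alone); adjusted p with an estimated correlation was 0.51 and 0.52. The stem cell marker Lgr5 fell from 6.54 ± 2.01 to 3.30 and 0.940 TPM, but not without B6 dam day 24 replicate 2 (adjusted p = 0.24). Limma called 1297 genes, 244 higher and 1053 lower, and 2085 after scaling, 1195 higher and 890 lower. The share higher was 18.8% as deposited and 57.3% scaled, with a shift of the median gene from -0.29 to 0.01, and 1030 genes passed in both. Without B6 dam day 24 replicates 1 and 2 the counts were 4291 and 486 (scaled 3539 and 951), and without B6 dam day 14 replicates 1 and 2 they were 796 and 695 (scaled without replicate 2, 1356).

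In pups of IgA-null dams, Reg3b rose between days 14 and 24 from 74.9 ± 39.5 to 1017 ± 116 TPM (log2 fold change 3.86, SE 0.48, adjusted p = 2.0e-05), Reg3g from 20.1 ± 22.0 to 270 ± 83.1 and Duox2 from 0.665 ± 0.160 to 7.59 ± 1.5 TPM. Without IgA-null dam day 14 replicate 1 the log2 fold change of Reg3g was 4.97 in place of 4.15. Enpp7, an alkaline sphingomyelinase of the gut, rose from 1.98 ± 0.409 to 33.4 ± 16.8 TPM. Nts fell from 218 ± 61.5 to 3.52 ± 2.74 TPM, Pyy from 37.6 ± 6.64 to 1.06 ± 0.524, and Fcgrt from 184 ± 70.4 to 7.02 ± 0.874 (SD, n = 3 each). Of the lists, microbe-responsive (8 of 15 higher, 4 lower), MHC class II (4 of 7 higher), interferon-stimulated (8 of 26 higher, 2 lower), mitochondrially encoded (6 of 13 higher) and T cell (3 of 5 higher) genes held with an estimated correlation (adjusted p = 0.0028, 0.012, 0.049, 0.019 and 0.038), and none did after scaling. Adjusted over the list alone 8, 4, 3, 1 and 3 members were higher. Neonatal enterocyte genes fell in 16 of 18 (16 adjusted over the list alone, 8 in both scalings), enteroendocrine genes in 17 of 20 (17 and 6) and cell cycle genes in 28 of 28 (28 and 11). With an estimated correlation their adjusted p was 0.73, 0.92 and 0.63. As deposited, 12497 of all 15066 genes fell, so a fall of most members says little about these lists.

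As deposited, limma called 12627 genes in this comparison, 130 higher and 12497 lower, with a median log2 fold change of all genes of -1.02 (scaled -0.02). After scaling it called 2505 genes, 1258 higher and 1247 lower, so that the share higher went from 1.03% to 50.2%, and 1371 genes passed in both. Without IgA-null dam day 14 replicates 2 and 3 and day 24 replicate 2 the scaled counts were 1200, 1240 and 1449. With scaling, 644 genes rose in both dam groups between days 14 and 24, against 99.8 expected if the calls were independent, and 445 fell in both, against 73.7. Calls in opposite directions numbered 18 and 1, and the Pearson r of the age changes across all genes was 0.666.

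In pups of IgA-null dams, enteroendocrine and tuft cell genes were higher at day 42 than at day 24. Nts rose from 3.52 ± 2.74 to 38.4 ± 9.09 TPM (log2 fold change 3.26, SE 0.45, adjusted p = 0.0023), Gcg, the proglucagon gene, from 12.2 ± 2.62 to 113 ± 17.1 TPM, and Sst, somatostatin, from 41.5 ± 17.3 to 297 ± 107 TPM. Rgs13, a tuft cell signalling gene, rose from 1.31 ± 0.548 to 16.7 ± 13.9 TPM, with a log2 fold change of 2.70, or 2.10 without IgA-null dam day 42 replicate 1. S100g, which carries calcium through the enterocyte, fell from 194 ± 101 to 20.4 ± 8.47 TPM, and Ifit1, an interferon-stimulated gene, from 10.2 ± 4.94 to 0.924 ± 0.330 TPM (SD, n = 3 each). Of the enteroendocrine list 19 of 20 rose and of the tuft list 17 of 17 (19 and 17 adjusted over the list alone, 13 and 10 in both scalings; adjusted p = 0.40 each with an estimated correlation). Interferon-stimulated genes fell in 9 of 26 (9 adjusted over the list alone, 9 in both scalings; adjusted p = 0.17 with an estimated correlation). Limma called 7434 genes, 7304 higher and 130 lower, and 388 after scaling, 217 higher and 171 lower (98.3% and 55.9% higher; median gene 0.53 and 0.01; 293 in both). Without IgA-null dam day 24 replicates 2 and 3 and day 42 replicate 1 the counts were 4879, 3882 and 4343. The scaled counts were 72 without day 24 replicate 1, and 42, 126 and 102 without day 42 replicates 1, 2 and 3.

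With the B6 dam, limma called 3 genes between days 24 and 42. The 2 day 24 libraries had the lowest Pearson r of any replicate pair (0.915), so this small count does not show that little changed. Ceacam10, a member of the carcinoembryonic antigen family (chromosome 7, 24777206 to 24784657), rose from 0.613 and 0.796 to 5.16 ± 1.38 TPM (log2 fold change 1.83, SE 0.19, adjusted p = 0.00080). H2-Aa, an MHC class II chain, rose from 0.908 and 1.27 to 8.10 ± 0.631 TPM (adjusted p = 0.042, scaled 0.20). Igf2bp3, an RNA-binding protein of fetal tissue, fell from 2.34 and 1.52 to 0.286 ± 0.137 TPM (SD, n = 3; adjusted p = 0.035). No MHC class II gene but H2-Aa passed over all genes, while 7 of 7 were higher adjusted over the list alone (median 1.55), and 16 of 26 interferon-stimulated genes were lower adjusted over the list alone (median -1.02). Both lists passed camera, with adjusted p = 0.068 each with an estimated correlation. Limma called 4 genes after scaling, 2 of them shared, and limma-voom 4. H2-Aa and Igf2bp3 lost the call without B6 dam day 24 replicate 1 (adjusted p = 0.085 and 0.077), among other libraries. Without that library the count was 19 (760 after scaling), without B6 dam day 42 replicates 2 and 3 it was 1 each, and after scaling it was 2 without replicate 3.

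**Figure D3:**
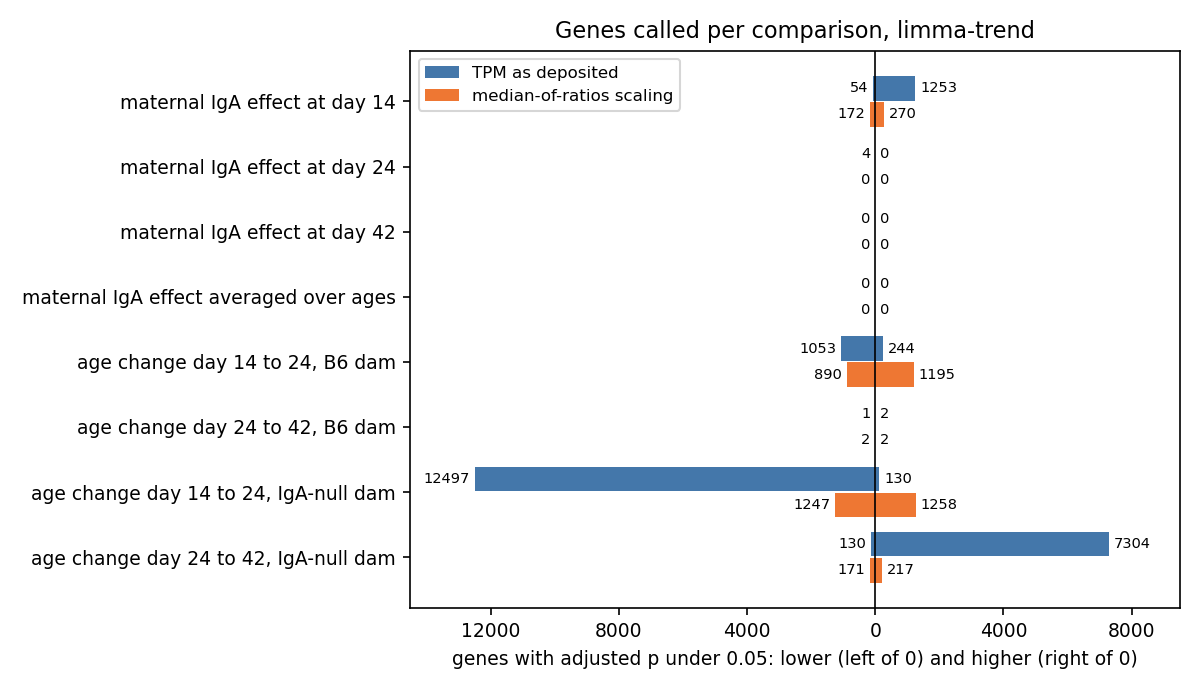
Number of genes past an adjusted p of 0.05 in each comparison, higher to the right of 0 and lower to the left, as deposited and after median-of-ratios scaling. As deposited, 12497 genes were lower from day 14 to day 24 with the IgA-null dam, against 1247 after scaling.

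The enterocyte maturation score rose from day 14 to day 24 in both dam groups. At day 14 it was -1.55 ± 0.449 with the B6 dam and -0.537 ± 0.298 with the IgA-null dam (SD, n = 3 each), and every IgA-null library lay above every B6 library. The difference of 1.02 had an exact two-sided p = 0.10, the smallest that 3 against 3 libraries allow. After scaling, the day 14 neonatal list score was 1.69 ± 0.659 with the B6 dam and 0.527 ± 0.202 with the IgA-null dam. The adult list score was -0.441 ± 0.253 and -0.566 ± 0.385 (SD, n = 3 each), so adult genes were not higher with the IgA-null dam. Differences in the maturation score at days 24 and 42 were -0.352 (exact p = 0.80, smallest possible 0.20) and -0.327 (exact p = 0.70). From day 14 to day 24 the score differed by 3.46 with the B6 dam (exact p = 0.20, the smallest possible) and by 2.09 with the IgA-null dam (exact p = 0.10, the smallest possible). Without B6 dam day 24 replicates 1 and 2 the day 24 difference was -1.24 and 0.531, and without B6 dam day 42 replicate 1 the day 42 difference was 0.115. The steps from day 24 to day 42 were -0.533 (exact p = 0.40) and -0.507 (exact p = 0.10).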

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

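The permutations of the samples and the test of gene length were planned; the other tests of the 3 patterns weighed here were chosen after the results were seen.

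The effect of the dam differed between ages, by limma's moderated F test of the difference itself, in each of the following results. The dates in the labels differed between the dams at days 14 and 24 but not at day 42. A batch that follows the date therefore cannot be told apart from these differences. For Reg3b (adjusted p = 0.00663) the log2 fold change at days 14, 24 and 42 was 4.23, -1.30 and -1.22, and for Zg16 (0.0115) it was 3.63, -0.23 (scaled 0.35) and -0.68. Among hormone and granule genes, Nts (0.00797) had 3.07, -2.46 and 0.14, Pyy (0.0115) had 2.60, -2.05 and 0.23, Sct (0.0128) had 2.45, -1.88 and 0.16, Pcsk1n (0.0122) had 1.81, -0.50 and 0.28, and Tph1 (0.0252) had 2.06, -0.82 and 0.62. Afp (0.0166) had 2.28, -0.91 and 0.71, Fer1l6 (0.0252) had 1.63, 0.17 and -0.11 (scaled 1.19, 0.60 and -0.16), and Slc35g1 (0.0239) had 0.51, -1.14 and -0.03 (scaled 0.09, -0.64 and -0.08). After scaling, Reg3b, Nts, Pyy, Pcsk1n, Sct and Tph1 passed at 0.0480 each, while Zg16 (0.0744), Afp and Fer1l6 (0.0806 each) and Slc35g1 (0.504) did not. No gene passed after scaling without B6 dam day 14 replicate 1, IgA-null dam day 14 replicate 1 or 2, or IgA-null dam day 24 replicate 3. The same held without B6 dam day 42 replicate 2 and without IgA-null dam day 42 replicate 1 or 3. As deposited, none passed with TPM without mitochondrial and the 50 highest genes, or with the covariate from Xist and Y-linked genes. That covariate followed the size factors of the libraries, so its result does not show an effect of sex. Some calls were lost without 1 day 14 library: Slc35g1 without B6 dam replicates 1 and 2 (adjusted p = 0.065 and 0.054) and IgA-null dam replicates 1 and 3 (0.059 and 0.051), Fer1l6 without the same 4 libraries (0.065, 0.062, 0.068 and 0.062), and Tph1 without B6 dam replicate 1 (0.068) and IgA-null dam replicates 1 and 3 (0.059 and 0.061). Without B6 dam day 24 replicate 1, Tph1 (0.060) and Afp (0.052) lost the call. In limma's camera with an estimated correlation, the mitochondrially encoded list differed between days 14 and 24 (adjusted p = 0.0440; medians -0.53 and 0.46; scaled adjusted p = 0.201) and the Paneth cell list between days 24 and 42 (adjusted p = 0.0350; medians 1.82 and -0.88; scaled adjusted p = 0.270). The day 42 side of the Paneth cell result rests on 1 library. Relative to the median of all genes, that list's day 42 median was -0.91, but -0.042 without B6 dam day 42 replicate 1.

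The dam labels were permuted within ages. As deposited, 4 of 100 splits, the real one included, gave at least the 264 genes of the real split. The highest of the other splits gave 2969 genes, several times the real count, which points to a structure of the samples; it kept the real groups of days 14 and 42 and exchanged B6 dam day 24 replicate 2 with IgA-null dam day 24 replicate 1. After scaling, 7 of 100 splits gave at least the 21 genes of the real one (highest other 184). Chance cannot be excluded in either scaling. The share as deposited was small, but it was larger after scaling. In each scaling a wrong grouping also gave more genes than the real one.

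Goblet and enteroendocrine genes were higher at day 14 with the IgA-null dam: of 40 members 35 were called, 27 in both scalings. A shift of all TPM by abundant non-coding RNA is argued against by their scaled median log2 fold change of 1.59 (quartiles 0.96 and 1.89), and gene length bias by a median difference of 1.56 (quartiles 0.98 and 1.86) from genes of like length. A smaller share of villus enterocytes as the whole cause, which would raise stem cell genes alike, is argued against by the scaled stem cell median of -0.23 (quartiles -0.32 and -0.08). The scaled neonatal enterocyte score was lower with the IgA-null dam (0.527 against 1.69), so a smaller share as a part of the cause stays open. A batch that follows the date in the labels cannot be told apart from the dam, since the dams share 0 dates at day 14. At day 42, the only age at which the dams share a date, 0 genes were called in either scaling. Age differs there as well, so this does not decide between a batch and the dam. The day 14 IgA-null dam libraries also held more Rn7sk (3.11% against 0.679% of TPM) and more genes at a TPM of 1 (13212 to 14257 against 11883 to 12305). They held fewer mitochondrially encoded transcripts (scaled list median -0.97). An effect of maternal IgA stays open as a hypothesis, as do whatever made the libraries differ in composition and any other difference between the litters.

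In scaled adult enterocyte scores the 2 B6 dam day 24 libraries lay on both sides of the IgA-null dam day 24 libraries (-0.50 and 2.49, against 0.70 to 0.86). B6 dam day 42 replicate 1 (1.58) lay above the others of its group (-0.76 and -0.63). Without day 24 replicates 1 and 2 and day 42 replicate 1, the 264 genes of the difference between ages became 26, 6555 and 1632. A swap of labels between the replicates numbered 1 is argued against by 24 genes that moved 1 way with age in the IgA-null dam groups: on a scale from 0 (day 24) to 1 (day 42) the day 42 library had a median of 0.76 (quartiles 0.64 and 0.94). A wrong age label on day 24 replicate 1 alone cannot be told apart, since its median was 0.66 with quartiles of 0.26 and 0.73, on both sides of the midpoint, against 0.07 for replicate 2. After scaling, list members were compared in day 24 replicate 2 over replicate 1 and in day 42 replicate 1 over the others. A different share of villus enterocytes as the whole cause is argued against by Paneth cell members, which were higher (0.72, quartiles 0.39 and 1.16, and 3.12, quartiles 2.61 and 3.31). Stem cell (-0.76 and -0.25), cell cycle (-0.41 and -0.10) and enteroendocrine members (-0.35 and -1.05) had lower medians, as a larger share would give. Goblet members had medians of 0.18 and 0.07, and tuft members of 0.15 and -0.315. Paneth cell recovery may vary by itself, so a different share as a part of the cause stays open. No biological explanation was tested.

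The scaled Paneth cell score was 2.30 higher at day 24 with the IgA-null dam. As deposited, 0 of 18 members passed over all genes in limma (12 adjusted over the list alone), and camera's adjusted p was 0.051 with an estimated correlation. Recovery of Paneth cells that varied between libraries of 1 group cannot be told apart from the higher score. Within the 3 B6 dam day 42 libraries the score ran over a range of 3.41 (-1.23 to 2.18), but replicate 1 alone carried it, and without that library the range was 0.92. In the other groups the SD of the score was 0.243 to 0.646. The dates in the labels differ between the dams at day 24. A batch that follows the date therefore cannot be told apart from the dam. An effect of maternal IgA stays open as well, as untested.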

How the results depend on the processing

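Most alternatives were planned; limma-voom, leaving out libraries after scaling, and leaving out pairs of doubted libraries were chosen after seeing the data.

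Of the 153 named gene results, alternatives other than leaving out a library gave the same direction and side of the threshold in 1687 cases, lost the call in 253, gained one in 32 and reversed 2; leaving out 1 library gave 917, 126, 17 and 0. For the 54 list results between dams called by camera, other settings kept 94 calls and lost 68, and leaving out 1 library kept 402, lost 38 and reversed 15. At day 14, Reg3b, Zg16, Chga, Chgb, Gpx3, Lgmn, Ctsl, Tff3, Muc2, Fer1l6, Tph1, Mptx1 and Csf1r kept their calls under every alternative in which they were tested. For counts of genes that moved by over 1.5 times the cause was not tested.

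Counts of called genes changed as follows. With a pseudocount of 0.1, day 14 gave 534, day 24 gave 425 and the difference between ages 161; with 5, day 14 gave 2489 and the difference between ages 608. Without a filter, day 24 gave 22, day 42 gave 5, the average over ages 13, days 24 to 42 with the B6 dam 16 and the difference between ages 97. With a TPM of at least 5, fewer genes were tested, and day 14 gave 673, day 24 gave 909, days 14 to 24 with the B6 dam 785, days 24 to 42 with the B6 dam 0, days 14 to 24 with the IgA-null dam 6733 and days 24 to 42 with the IgA-null dam 4864.

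Median-of-ratios scaling gave 442 at day 14, 0 at day 24, 2085 for days 14 to 24 with the B6 dam, 2505 and 388 for the adjacent ages with the IgA-null dam, and 21 for the difference between ages. Quantile normalisation gave 680 at day 14, 0 at day 24, 1 on average, 2373 and 631 with the IgA-null dam, and 14 between ages. TPM without mitochondrial and the 50 highest genes gave 300 at day 14, 0 at day 24, 1970 and 5 with the B6 dam, 2468 and 1150 with the IgA-null dam, and 0 between ages. Limma-voom on recovered reads gave 416 at day 14, 0 at day 24, 14 on average, 2105 with the B6 dam from day 14 to 24, 1690 and 285 with the IgA-null dam, and 6 between ages.

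Robust moderation gave 2 at day 24. Library weights, whose estimate did not converge and ran from 0.202 to 49.9, gave 8581 at day 14, 0 at day 24, 883 at day 42, 339 and 1 with the B6 dam, 11693 from day 24 to 42 with the IgA-null dam and 8372 between ages; under them Fabp1 at day 42 reversed to 0.090. With only the compared groups fitted, fewer samples gave 3035 at day 14, 0 at day 24, and 69 and 0 with the B6 dam. A covariate from Xist and Y-linked genes varied from -0.692 to 0.759 although every library was Y-positive. It was lowest in the IgA-null dam libraries of day 14 (-0.293 to -0.692, at size factors of 1.40 to 1.83). It was highest in those of day 24 (0.389 to 0.759, at size factors of 0.717 to 0.477). Scaled Ddx3y lay between 4.50 and 5.84 TPM in every library. The covariate thus followed the size factors, and its counts do not show an effect of sex. With it, day 14 gave 81, day 24 gave 1, the average 2, the IgA-null dam 12 and 3 and the difference between ages 0. Under it Cyp2b10 from day 14 to 24 with the IgA-null dam reversed to -0.11. With a replicate block, day 24 gave 2, the B6 dam 845 and 1 and the difference between ages 58; samples with a shared number correlated at -0.649 to 0.261 over 18 pairs, with 3 above 0.1, so the numbers give no sign of pairing.

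Counts with 1 library left out ran as follows, where B6 dam day 24 then holds a lone sample assumed to vary like the other groups. Day 14 ran from 324 to 1267 (scaled 82 to 545), day 24 from 0 to 4870 (scaled 1 to 29), and the average from 0 to 16 (scaled 0 to 85). Days 14 to 24 with the B6 dam ran from 486 to 4291 (scaled 951 to 3539) and days 24 to 42 from 1 to 19 (scaled 2 to 760). With the IgA-null dam the ranges were 1200 to 2571 (scaled) for days 14 to 24, and 3882 to 8797 (scaled 42 to 399) for days 24 to 42. The difference between ages ran from 9 to 6555 (scaled 0 to 133). Leaving out B6 dam day 42 replicate 1 with day 24 replicate 1 gave 2 on average, 3849 for days 24 to 42 with the B6 dam and 455 between ages (scaled 282, 2251 and 194). With day 24 replicate 2 in its place the counts were 62, 1 and 7798 (scaled 16, 2 and 187).

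Of 29 lists, the number past camera fell with an estimated correlation to 0 at each age, on average, for days 24 to 42 with each dam, to 1 for days 14 to 24 with the B6 dam and to 5 with the IgA-null dam. By fry it was 3 at day 14, 7 at day 24, 0 at day 42, 0 on average, 6 and 1 with the B6 dam and 13 for days 24 to 42 with the IgA-null dam, but 20 for days 14 to 24 with the IgA-null dam, above the 16 past camera. Fry was run only as deposited, so shifts of all genes enter its counts. The median log2 fold change of all genes was -1.02 for days 14 to 24 with the IgA-null dam. With 1 library left out the number past camera ran from 9 to 21 at day 24, 6 to 19 at day 42 and 10 to 18 for days 24 to 42 with the B6 dam. The maturation difference at day 14 was 1.53 with the median of the members.

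Camera's direction changed in these lists when 1 library was left out; values are list medians relative to the median of all genes. Cell cycle genes at day 24 ran from -0.53 to 0.11, the latter without B6 dam replicate 1. At day 42 adult enterocyte genes ran from -0.91 to 0.22, Paneth genes from -1.67 to -0.042, fat absorption from -0.80 to 0.044, peptide uptake from -0.81 to 0.070, aryl hydrocarbon genes from -0.41 to 0.13, immediate early genes from -0.36 to 0.017, proximal genes from -0.32 to 0.054, distal genes from -0.68 to 0.12 and T cell genes from -0.93 to 0.16. Each of these highest values came without B6 dam replicate 1. Averaged over ages, adult enterocyte genes ran from -0.78 to 0.12, fat absorption from -0.77 to 0.046, peptide uptake from -0.81 to 0.042 and aryl hydrocarbon genes from -0.46 to 0.064, without B6 dam day 24 replicates 1 and 2 in turn.

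Depth limits the precision of low genes: 4025955 to 5181585 reads lay outside Gm23935 and mitochondrial genes in the IgA-null dam day 24 libraries, the fewest of any group.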

Other observations

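The clock test here was chosen after the result was seen, while the permutations of the samples were planned.

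After scaling, cholesterol synthesis genes were higher at day 24 than at day 14 in 13 of 22 members with each dam (18 and 15 adjusted over the list alone), and nuclear electron transport genes in 17 of 42 with the B6 dam and 18 with the IgA-null dam (37 and 26 adjusted over the list alone). As deposited the direction flipped with the IgA-null dam, where 17 and 42 members were lower, and with the B6 dam 2 and 0 were higher. Scaled adjusted p with an estimated correlation was 0.13 and 0.17 for cholesterol synthesis and 0.30 and 0.45 for electron transport.

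For comparisons of 3 against 3 libraries only 10 splits exist, which are too few for a share under 0.05. At day 14 the real split gave 1307 genes and the highest other 5 (scaled 442 and 2), and 1 of the 10 splits was as large in each scaling. At day 42 the real split gave 0 genes and the highest other 1 in each scaling. For days 14 to 24 with the IgA-null dam the real split gave 12627 and the highest other 3 (scaled 2505 and 1), and for days 24 to 42 it gave 7434 and 0 (scaled 388 and 0), with 1 of 10 as large in each case. For the average over ages, limma called 0 genes in the real split, so that 100 of 100 splits were at least as large in each scaling by construction, which says nothing about chance. The same holds for the 10 of 10 at day 42. The highest other split of the average gave 5742 genes as deposited and 43 after scaling. The split with 5742 kept the real groups of day 14 and placed IgA-null dam day 24 replicates 2 and 3 with the B6 dam, and at day 42 it placed IgA-null dam replicates 1 and 2 there with B6 dam replicate 1. The median log2 fold change of all genes was 0.33 at day 14 and -0.38 at day 24, and no other structure of the samples was tested.

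Lower Nr1d2, Usp2 and Car4 at day 24 with the IgA-null dam may reflect collection at another clock phase. A clock score, the mean of 6 antiphase genes minus that of 8 E-box genes and without Nr1d2, was -0.308 ± 0.104 with the B6 dam (n = 2) and 0.641 ± 0.256 with the IgA-null dam (SD, n = 3), a difference of 0.949. Every IgA-null library lay above both B6 libraries (exact two-sided permutation p = 0.20, the smallest possible). At days 14 and 42 the differences were 0.226 and -0.149 (exact p = 0.10 each, the smallest possible). The labels give no time of day, and their dates differ between the dams at day 24, so the hypothesis remains open.

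The sample descriptions begin with F or M, which follows the dam and is not explained. Every library held Y-linked transcripts, with Ddx3y from 2.46 to 9.50 TPM.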
